A study of Mus musculus with 12 samples.

How the data were processed

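Gene expression was measured in ovaries of 12 adult female mice, 4 per diet group, which the series design states to be biological replicates. Per the labels, ovaries were removed and minced, total RNA was extracted on RNeasy columns, and it was amplified and labelled with Cy3 or Cy5 by a low-input 2-colour kit. Odd replicates carry Cy3 and even replicates Cy5. Per the file headers, the 6 arrays were read with Agilent Feature Extraction 11.0.1.1, and probe positions refer to build mm9; no gene annotation of that build was used here, so positions are given without exon or UTR. Each scanner file holds both samples of an array.

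The deposited scanner files give the mean signal and the median local background of each spot as intensity, without normalization. They also give a processed signal in intensity units, which per the file headers is background-subtracted, detrended and dye-normalized within the array. The deposited value table holds log2 values with the median of each column at 0, as tested on the values; how the authors made it is not stated. Its columns matched log2 of the mean signal minus the background (slopes 1.00188 to 1.00324 for the 8 control and early-life columns). It was used only as an alternative and to test the naming of the samples, and 99 to 10099 probe features of a column have no value.

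Of 44397 features, 1377 are controls and 43020 measure transcripts with 39429 distinct probes. Probes were named through the RefSeq accession (27234), a symbol in the RefSeq table (3576) or a synonym (565), and the rest (8054) keep the name in the file. Values were computed with R 4.3.3 and limma 3.58.1, with the packages data.table (1.17.8) and statmod (1.5.0). Background was removed by normexp with an offset of 50, arrays were normalized by loess within and Aquantile between arrays, and the channels were then treated as separate log2 values. Spots that the software set aside as outliers (2.16% to 4.28% of a channel) were left out, so that 3.16% of values are missing. Probes well above background in at least 4 of 12 samples were kept (23791), and the brightest probe stood for each of the 18559 genes and transcripts tested, of which 15343 names are in the RefSeq table. A group with no sample above background in a named gene gives a lower bound of the fold, computed against its background level. Signal over background was 6.96 to 9.62, and the number of arrays limits the precision.

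The 3 groups were compared in 1 limma model with dye as covariate and the array as random block (correlation 0.288), with Benjamini-Hochberg adjusted p under 0.05 over all genes. The standard errors are those of this model. In data simulated from the model with 200 changed genes, 29.9% to 34.3% of 1.5-fold and 71.6% to 77.6% of 2-fold changes were recovered. Of 4-fold changes, 90.9% to 93.9% were. False calls numbered 13 to 14 among 141 to 151, a larger share than the threshold of 0.05 aims at. The array correlation was estimated at 0.225 to 0.234 there, under the 0.288 simulated. The calls given below may thus hold more false ones than the threshold implies. Gene lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation, and with fry, all from limma. The 30 lists are vitamin D signalling, steroidogenesis, cholesterol synthesis and uptake, hormone receptors, LH-responsive periovulatory genes, the TGF-beta, AMH and inhibin family, the insulin and IGF axis, the WNT pathway, the cell cycle, apoptosis, extracellular matrix, angiogenesis, oxidative phosphorylation, immediate-early genes, heat shock, the circadian clock and the interferon response, and markers of oocyte, granulosa cell, theca cell, luteal cell, ovarian surface epithelium, oviduct epithelium, adipocyte, smooth muscle, endothelium, macrophage, lymphocyte, granulocyte and red blood cell. The median, mean and test of a list differed in sign in 5 lists for early life versus control, 6 for peripubertal versus control and 5 for early life versus peripubertal, and none of these lists passed. The oviduct score is the mean of the oviduct list in a sample.

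The groups, the lists, the tests, the alternatives other than those named as added, and the rule for named genes were chosen before the data were examined. Named genes are, per comparison, up to 10 with the largest rise and up to 10 with the largest fall among those that passed with all values of the groups apart, without clone, predicted-locus and transcript identifiers; where fewer than 10 pass, genes with the smallest p are added up to 10 and given as values. Always named are Vdr, Cyp24a1, Cyp27b1, Star, Cyp11a1, Cyp17a1, Cyp19a1, Fshr, Lhcgr, Esr1, Esr2, Pgr, Amh, Inha and Gdf9, and up to 4 members with the smallest p of each list that passed camera or had a member passing over the list alone. The cilia, pituitary and brain genes and other members of the oviduct list given as values were named to test explanations. Alternatives were other background, normalization, filter, probe and spot choices, the value table, other models of array, dye, replicate number and variance, a fold threshold, only 2 groups, and each sample and each array left out. The control and early-life arrays exchanged as in the value table, and the oviduct score as covariate, were added after the data were seen. A slide block exists only for early life versus control, which lies within 1 slide. Replicate numbers were used as pairs only in an added test of the oviduct score and as a block in an alternative. The overlap of effects that share controls was set against data simulated without an effect.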

Results

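Ovaries of 12 female C57BL/6J mice, an inbred laboratory strain, were profiled at 2 months of age on 2-colour Agilent arrays, on which RNA labelled with Cy3 or Cy5 binds to printed probes. The 3 diet groups held 4 females each. Control mice ate a normal diet, early-life mice lacked dietary vitamin D during early life only, and peripubertal mice lacked it around puberty only. Vitamin D is the precursor of a hormone that acts through the vitamin D receptor, Vdr. Samples are named C1 to C4 (control), E1 to E4 (early life) and P1 to P4 (peripubertal). Each of the 6 arrays carried 2 samples of 1 group, the odd replicate in Cy3 and the even in Cy5. The control and early-life arrays lay on 1 slide and the peripubertal arrays on the other, so slide and peripubertal diet cannot be told apart. The median probe signal of a channel was 147 to 331 intensity units, 6.96 to 9.62 times its background of 17.5 to 35 units, and 59.3% to 65.5% of probes were well above background. The number of arrays limits the precision of every value. Differences are log2 values with standard errors, group means are log2 intensities with SD, and adjusted p values are those of limma over all 18559 genes and transcripts tested unless a list is named.

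Group names are those that the labels give to the scanner files. In the deposited value table of the same samples, each of the 8 control and early-life columns matched a scanner channel of the other of these groups, with a correlation across features of at least 0.9998. Which deposit names the arrays correctly is not settled. The sign of every early-life difference from control is therefore open, and with the control and early-life arrays exchanged the comparison of peripubertal with control mice becomes the one of early-life with peripubertal mice and the reverse.

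The comparison of early-life deficiency with the control diet asks which ovarian transcripts differ in adulthood after a deficiency that was confined to early life. Interferon-response genes, which cells turn on in antiviral defence, fell as a group in early-life ovaries, as did macrophage markers and endothelial, angiogenesis and smooth muscle genes, while markers of the oviduct epithelium, fat cells and red blood cells rose. With an estimated correlation none of these 8 lists passed (adjusted p = 0.473 for each), and the endothelial call ended without C3, C4, E1 or E4. No single gene passed the test. The signs of all these differences are those of the scanner labels and turn with the arrays exchanged.

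The interferon list had a median log2 difference of -0.58 over 20 measured members (limma camera, adjusted p = 1.36e-06; adjusted p = 0.473 with an estimated correlation). Of its members 9 were lower and 0 higher when adjusted over the list alone, and 0 passed over all genes. Ifit3, an interferon-induced antiviral protein, measured 9.01 ± 0.26 (SD, n = 4) in early-life and 10.46 ± 0.60 (SD, n = 4) in control ovaries, a difference of -1.45 ± 0.29 (adjusted p = 0.138). Ddx58, a cytosolic sensor of viral RNA, differed by -0.64 ± 0.11 (adjusted p = 0.0982). Mx2, an antiviral GTPase, differed by -0.86 ± 0.18 and Ifit2 by -0.47 ± 0.11. In each of these 4 genes every early-life sample lay under every control sample. The macrophage list had a median of -0.75 over 12 members (camera adjusted p = 1.37e-05; adjusted p = 0.473 with an estimated correlation), with 10 members lower when adjusted over the list alone and 0 over all genes. C1qa and C1qb, subunits of complement component C1q, differed by -0.87 ± 0.24 and -0.94 ± 0.27. Adgre1, the macrophage surface protein F4/80, differed by -0.76 ± 0.21 and the mannose receptor Mrc1 by -0.70 ± 0.20.

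Endothelial markers had a median of -0.26 (camera adjusted p = 0.0406; adjusted p = 0.473 with an estimated correlation) and angiogenesis genes -0.26 (adjusted p = 0.0114; 0.473 as adjusted p with an estimated correlation). Emcn, an endothelial sialomucin, differed by -0.48 ± 0.17, the VEGF receptor Kdr by -0.23 ± 0.10, the VEGF co-receptor Nrp1 by -0.44 ± 0.15 and the ephrin receptor Ephb4 by -0.26 ± 0.078. Smooth muscle markers had a median of -0.59 (adjusted p = 0.00249; adjusted p = 0.473 with an estimated correlation). The contractile genes Smtn, Mylk and Acta2 differed by -0.40 ± 0.13, -0.49 ± 0.20 and -0.63 ± 0.34. In these 3 lists 0 members passed when adjusted over the list alone and 0 over all genes. The endothelial and angiogenesis lists are not independent, since 3 of the 10 endothelial members, Kdr, Tek and Tie1, are in both. Without 1 sample the endothelial list no longer passed (camera adjusted p = 0.0679 without C3, 0.107 without C4, 0.167 without E1 and 0.0596 without E4).

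Oviduct epithelium markers had a median of 1.64 over 13 members (camera adjusted p = 4.50e-05; adjusted p = 0.473 with an estimated correlation). Wfdc2, a protein secreted by reproductive tract epithelium, measured 13.20 ± 1.58 (SD, n = 4) in early-life and 10.08 ± 1.23 (SD, n = 4) in control ovaries, and the epithelial transcription factor Elf3 differed by 1.62 ± 0.65. Adipocyte markers had a median of 1.73 (adjusted p = 8.64e-05; adjusted p = 0.473 with an estimated correlation). Cfd, the protease adipsin, differed by 2.96 ± 1.17, the hormone gene Adipoq by 2.34 ± 0.93 and the fatty acid carrier Fabp4 by 2.59 ± 1.07, each higher in all 4 early-life samples than in all controls. Red blood cell markers had a median of 1.04 (camera adjusted p = 0.00111, and adjusted p = 0.473 with an estimated correlation). The globin genes Hba-a1 and Hbb-bs differed by 1.21 ± 0.61 and 1.58 ± 0.61. The groups overlapped in the mean of this list: C3, at 13.09, lay above E2, E3 and E4 (12.08, 12.32 and 13.08) and under E1 (13.87). Ovarian surface epithelium markers had a median of 0.60 (adjusted p = 0.00309; adjusted p = 0.492 with an estimated correlation), with the cadherin Cdh1 at 1.53 ± 0.86. In these 4 lists 0 members passed over the list alone and 0 over all genes.

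The mean of the oviduct list per sample, as a deviation from the mean of the 12 samples, was 1.58 ± 1.44 (SD, n = 4) in early-life, -0.27 ± 1.20 in control and -1.32 ± 0.46 in peripubertal samples. E2 had the lowest score of its group, -0.45, against 2.41 in E1, 1.59 in E3 and 2.78 in E4. The early-life samples lay higher in 14 of 16 pairs with a control (exact permutation test, two-sided, p = 0.114, and 0.171 adjusted over 3 comparisons). In all 3 comparisons this test treats samples as exchangeable, though each array holds 2 samples of 1 group. Taken as pairs by replicate number, a test added after the values were seen, the early-life sample lay higher in 4 of 4 (by 0.84 to 2.85; exact sign-flip permutation p = 0.125, two-sided, the smallest that 4 pairs allow). With this score as a covariate, a setting also chosen after the values were seen, the oviduct list lost its call by construction, and 6 of the other 13 lists no longer passed. Their medians went from 0.60 to -0.13 for surface epithelium, from -0.23 to -0.046 for cell cycle and from -0.69 to -0.35 for cholesterol genes, with median standard errors of members of 0.40 and 0.35, 0.20 and 0.19, and 0.48 and 0.56. They went from -0.26 to -0.20 for angiogenesis, from -0.26 to -0.21 for endothelium and from -0.14 to -0.14 for oxidative phosphorylation, with standard errors of 0.19 and 0.19, 0.16 and 0.18, and 0.11 and 0.13. Among lists that still passed, medians went from -0.58 to -0.86 for interferon, 0.24 to 0.48 for oocyte and -0.59 to -0.62 for smooth muscle. Medians went from 1.73 to 1.25 for adipocyte, 1.04 to 0.92 for red blood cells, 0.35 to 0.29 for immediate-early genes and -0.75 to -0.74 for macrophage.

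**Figure D1:**
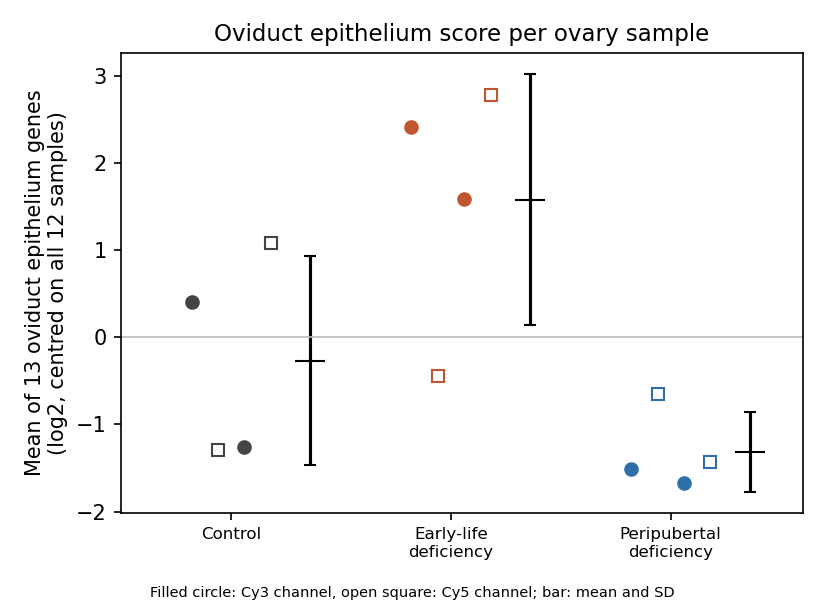
Oviduct epithelium marker score of each sample, the mean log2 value of the list as a deviation from the mean of the 12 samples, by diet group. Filled circles are Cy3 and open squares Cy5 samples, and bars are the mean and SD of 4 samples; E2, at -0.45, lies under the other early-life samples (1.59 to 2.78).

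Cholesterol synthesis and uptake genes fell as a group (median -0.69; camera adjusted p = 0.00309; adjusted p = 0.577 with an estimated correlation). Mevalonate kinase, Mvk, differed by -0.85 ± 0.30 and the sterol carrier Stard4 by -0.96 ± 0.38. Cell cycle genes fell (median -0.23; adjusted p = 6.50e-04; adjusted p = 0.492 with an estimated correlation), with the topoisomerase Top2a at -0.47 ± 0.14 and the mitotic kinase Cdk1 at -0.45 ± 0.18. Oxidative phosphorylation genes fell slightly (median -0.14; adjusted p = 0.0239; adjusted p = 0.473 with an estimated correlation), with Sdhb at -0.38 ± 0.11 but Sdha, of the same enzyme complex, at 0.74 ± 0.15 on 2 control values. Immediate-early genes, induced within minutes of a stimulus, rose (median 0.35; adjusted p = 1.71e-04; adjusted p = 0.473 with an estimated correlation). Fosb, at 0.96 ± 0.21, was the 1 member to pass when adjusted over the list alone, and Fos differed by 1.07 ± 0.35. Oocyte markers rose (median 0.24; adjusted p = 0.00733; adjusted p = 0.577 with an estimated correlation), with the zona pellucida gene Zp1 at 0.39 ± 0.23. Apart from Fosb, 0 members of these 5 lists passed over their list alone, and 0 of all passed over all genes.

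Single samples decided 3 of these calls. The oocyte list reached a camera adjusted p of 0.0565 without C4 and 0.374 without E2, oxidative phosphorylation 0.114 without C4 and 0.0802 without E1, and cholesterol 0.0976 without C4.

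In 3 lists that did not pass as a whole, members passed when adjusted over the list alone, and 0 did over all genes. The insulin receptor substrate Irs1 differed by 0.75 ± 0.16 and the PI3-kinase subunit Pik3r1 by 1.20 ± 0.31, while the IGF-binding protein family member Igfbp7 differed by -0.69 ± 0.20. The activin receptor Acvr2b differed by 0.52 ± 0.11 and the leukocyte antigen Ptprc (CD45) by -0.42 ± 0.12. Among the lists that did not pass the medians were -0.068 for vitamin D signalling, -0.30 for steroidogenesis, 0.14 for hormone receptors, -0.074 for LH-responsive periovulatory genes, 0.022 for the TGF-beta, AMH and inhibin family, 0.017 for the insulin and IGF axis, -0.038 for the WNT pathway, -0.045 for apoptosis, -0.12 for extracellular matrix, 0.24 for heat shock, -0.037 for the circadian clock, -0.013 for granulosa cell markers, -0.27 for theca cell markers, 0.076 for luteal cell markers, -0.074 for lymphocyte markers and -0.089 for granulocyte markers, with camera adjusted p of 0.0748 to 0.983.

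Limma called 0 genes in this comparison, while 2586 had an unadjusted p under 0.05 against 928 by chance, and the smallest adjusted p was 0.0503. The samples of the 2 groups did not overlap in 3181 genes (17.1%). Independent values, 4 against 4, would give 2.86% by chance. Here both samples of an array belong to 1 group, values were adjusted for dye and some are missing. The share by chance is therefore not known. The genes with the smallest p are given as values. Fam135a measured 9.73 ± 0.044 (SD, n = 4) in early-life and 8.10 ± 0.21 (SD, n = 2) in control samples. The olfactory receptor Olfr1357, the stefin family protease inhibitor Stfa2l1, the claudin family member Cldn34b4 and the Mas-related receptor Mrgpra1 were at background in early-life samples, at least 1.66-fold, 1.62-fold, 1.99-fold and 1.93-fold lower than in controls. Creb3l2, a transcription factor held in the endoplasmic reticulum membrane, differed by 1.76 ± 0.19 on 2 control values, and Wnk1, a kinase that regulates ion transport, by 1.28 ± 0.16 on 2 control values. The exportin Xpo7, the zinc finger gene Zfp608 and the G protein subunit Gngt2 differed by -0.62 ± 0.090, 0.69 ± 0.11 and -0.77 ± 0.12. The adjusted p of these 10 genes was 0.0503 to 0.0921. Without 1 sample the count was 108 without E2, 13 without C2, 2 without C3 and 1 without E4. Among the processings, 116 genes passed with no array block, 35 without the dye term, 21 with the software's processed signals, 10 with the intraspot model, 6 with trend and robust variance, 5 without background subtraction, 4 with quantile scaling and 1 with outlier spots kept. On the deposited value table, in which the groups are the other way round, 255 passed (165 higher, 90 lower). The spread of that fit also rests on the table's 4 peripubertal columns, which match no array. The 14 lists became 0 with an estimated correlation and 0 with fry, which tests a list on its own (2 and 6 of the 14 with an unadjusted p under 0.05).

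The comparison of peripubertal deficiency with the control diet asks what differs in adult ovaries after a deficiency around puberty. In peripubertal ovaries 50 genes changed, 19 higher and 31 lower. Snd1, Gcat and Dvl3, which act in RNA handling, glycine metabolism and WNT signalling, fell in all 4 samples. Transcripts of the vomeronasal receptor Vmn2r28 and the seminal vesicle protein Svs3a rose from background. Cell cycle genes fell as a group and macrophage markers rose. With an estimated correlation neither list passed (adjusted p = 0.903 for both), and the macrophage call ended without C4, P1 or P2. All peripubertal arrays were on their own slide, and with the control and early-life arrays exchanged the count is 471 (375 higher, 96 lower).

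Vmn2r28 (probe on chromosome 7, 5432165 to 5432224, build mm9) measured 10.02 ± 0.72 (SD, n = 4) in peripubertal samples and was at background in controls, at least 9.12-fold higher (adjusted p = 0.0161). Svs3a was at least 2.85-fold higher, and Cd300ld4, of the CD300 family of myeloid cells, at least 3.44-fold on 2 peripubertal values. Ccng1, cyclin G1 and a p53 target, rose by 1.74 ± 0.19, Fam135a by 1.51 ± 0.16, Wnk1 by 1.47 ± 0.16 and the endothelial tyrosine phosphatase Ptprb by 1.21 ± 0.15, each against 2 control values. Evi2a rose by 0.93 ± 0.12, the syntrophin Sntb1 by 0.68 ± 0.11 and Erp27, a protein of the endoplasmic reticulum, by 0.57 ± 0.095. Among the falls, Snd1 (probe on chromosome 6, 28838378 to 28838437) measured 10.24 ± 0.23 (SD, n = 4) in peripubertal and 11.74 ± 0.16 (SD, n = 4) in control samples, a difference of -1.49 ± 0.14 (adjusted p = 0.0124). The mitochondrial enzyme Gcat differed by -1.27 ± 0.13, dishevelled Dvl3 by -1.23 ± 0.14, Prcc by -1.33 ± 0.19 and Paip1, a partner of the poly(A)-binding protein, by -1.23 ± 0.19. The lysosomal potassium channel Tmem175 differed by -1.62 ± 0.13 on 2 peripubertal values, the protamine Prm1 by -0.99 ± 0.15 and Wdcp by -0.93 ± 0.14. Sntb1 was above background in 1 of 4 controls and Wdcp in 2 of 4 peripubertal samples. Mrgpra1 and Cldn34b4 were at background in peripubertal samples, at least 1.28-fold and 1.5-fold lower. In these 20 genes all values of the groups lay apart, with limma adjusted p of 0.0124 to 0.0492. Fam135a, Mrgpra1 and Cldn34b4 differed little between peripubertal and early-life samples (-0.028, 0.12 and 0.16, peripubertal minus early-life). As labelled, these calls thus set the controls apart from both deficient groups and are not particular to the peripubertal one. For 6 of the 50 genes another probe was above background, and 0 of these 6 probes reached an unadjusted p under 0.05 in the called direction. Among the named genes of this comparison, the other probe differed by 0.034 in Paip1, 0.19 in Ptprb and 0.083 in Sntb1.

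Cell cycle genes fell as a group (median -0.32 over 33 members; camera adjusted p = 2.38e-08; adjusted p = 0.903 with an estimated correlation). Cyclin E1, Ccne1, differed by -0.80 ± 0.16, lower in all 4 peripubertal samples, and was the 1 member to pass over the list alone, with 0 over all genes. Top2a and Cdk1 differed by -0.44 ± 0.11 and -0.61 ± 0.18. Macrophage markers rose (median 0.41; adjusted p = 0.0310; adjusted p = 0.903 with an estimated correlation), with the fractalkine receptor Cx3cr1 at 0.76 ± 0.23 and Adgre1 at 0.43 ± 0.21. Oviduct epithelium markers fell (median -1.08; adjusted p = 0.0310; adjusted p = 0.903 with an estimated correlation), with Wfdc2 at -1.38 ± 1.01 and the cilia regulator Foxj1 at -2.31 ± 1.54 (above background in 2 of 4 peripubertal samples); in these 2 lists 0 members passed over the list alone. The oviduct score was higher in peripubertal samples in 2 of 16 pairs (exact permutation p = 0.171, two-sided). Irs1, at 0.74 ± 0.17, passed over the insulin and IGF list alone and not over all genes. Without 1 sample the macrophage list reached a camera adjusted p of 0.349 without C4, 0.0779 without P1 and 0.25 without P2, and the oviduct list 0.181 without C1, 0.349 without C4, 0.0946 without P1, 0.0621 without P3 and 0.0550 without P4. Of the 3 lists that passed, 0 did with an estimated correlation and 0 with fry (0 and 1 of the 3 with an unadjusted p under 0.05). With the oviduct score as covariate the oviduct list lost its call by construction. Cell cycle and macrophage genes still passed, with medians from -0.32 to -0.49 and from 0.41 to 0.41. The number of lists that passed was 5 without C3, 5 without P3 and 1 without C4. The other lists had medians of 0.13 for vitamin D signalling, 0.20 for steroidogenesis, -0.22 for cholesterol synthesis and uptake, -0.0088 for hormone receptors, -0.041 for LH-responsive periovulatory genes, -0.021 for the TGF-beta, AMH and inhibin family, 0.17 for the insulin and IGF axis, 0.12 for the WNT pathway, -0.035 for apoptosis, 0.13 for extracellular matrix, -0.0053 for angiogenesis, -0.092 for oxidative phosphorylation, 0.21 for immediate-early genes, -0.094 for heat shock, 0.11 for the circadian clock, -0.061 for the interferon response, 0.075 for oocyte markers, 0.0084 for granulosa cell markers, 0.21 for theca cell markers, 0.16 for luteal cell markers, -0.082 for ovarian surface epithelium markers, 0.58 for adipocyte markers, 0.017 for smooth muscle markers, 0.16 for endothelium markers, 0.0090 for lymphocyte markers, -0.027 for granulocyte markers and 0.82 for red blood cell markers, with camera adjusted p of 0.0926 to 0.978.

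Unadjusted p was under 0.05 in 2116 genes, and groups did not overlap in 2992 genes (16.1%). The 2.86% that holds for independent values does not apply here, for the reasons given above. Of the 50 genes 42 differed by at least 1.5-fold, 11 had fewer than 4 values in a group, 8 were at background in peripubertal samples and 6 in controls. Without 1 sample the count was 5 without C1, 29 without C2, 15 without C3, 14 without C4, 1 without E1, 15 without E2, 0 without E3, 12 without E4, 22 without P1, 13 without P2, 18 without P3 (10 higher, 8 lower) and 8 without P4. Early-life samples enter through the shared spread. Snd1 was no longer called without E3, Vmn2r28, Gcat and Dvl3 without E1 or E3, and the other 16 named genes without 5 to 12 of the 12 samples. With the oviduct score as covariate the count was 0, as the median standard error of the 50 genes grew from 0.134 to 0.147 while their median size went from 0.94 to 0.93. It was 0 with only the 2 groups in the model, 0 without the scaling between arrays, 1 on array means, 14 with the replicate block, 14 with probes above background in all samples, 19 with the mean of probes, 21 without a filter, 26 with outlier spots kept, 81 without the dye term and 159 without the array block.

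Early-life and peripubertal deficiency were compared with each other to ask whether the time of deficiency matters, and this comparison is the direct test of the difference between their effects. In early-life ovaries 471 genes changed, 96 higher and 375 lower than in peripubertal ovaries. Without E2 the balance turned (881 higher, 697 lower). Macrophage, interferon, endothelial, theca and smooth muscle genes were lower in early-life samples. With an estimated correlation none of these lists passed (adjusted p = 0.726 for smooth muscle and 0.563 for the others), and the endothelial, theca and smooth muscle calls all ended without P2, among other samples. Wfdc2 and other oviduct epithelium markers were higher (as a list, adjusted p = 0.563 with an estimated correlation), together with Cbs, cystathionine beta-synthase, and the epithelial membrane protein Pdzk1ip1. All peripubertal arrays lay on a slide of their own, and with the control and early-life arrays exchanged the count is 50 (31 higher, 19 lower).

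Macrophage markers fell (median -1.20 over 12 members; camera adjusted p = 7.72e-07; adjusted p = 0.563 with an estimated correlation), with 11 members lower over the list alone and 5 over all genes. C1qa measured 10.34 ± 0.27 (SD, n = 4) in early-life and 11.70 ± 0.30 (SD, n = 4) in peripubertal ovaries and fell by 1.36 ± 0.24 (adjusted p = 0.0318). C1qb fell by 1.43, Adgre1 by 1.19 and Cx3cr1 by 1.30 (adjusted p = 0.0351, 0.0318 and 0.0317). Interferon-response genes fell (median -0.54; camera adjusted p = 3.80e-04; adjusted p = 0.563 with an estimated correlation), with 10 lower over the list alone and 4 over all genes. Ddx58 (probe on chromosome 4, 40151893 to 40151952) differed by -0.68 ± 0.11 (adjusted p = 0.0261), the guanylate-binding protein Gbp3 by -1.02 ± 0.18, Ifit2 by -0.51 ± 0.11 and Irf9, a transcription factor of interferon signalling, by -0.66 ± 0.14. Every early-life sample lay under every peripubertal sample in these genes. The oviduct score of the early-life samples lay above that of the peripubertal samples throughout (1.58 ± 1.44 against -1.32 ± 0.46).

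**Figure D2:**
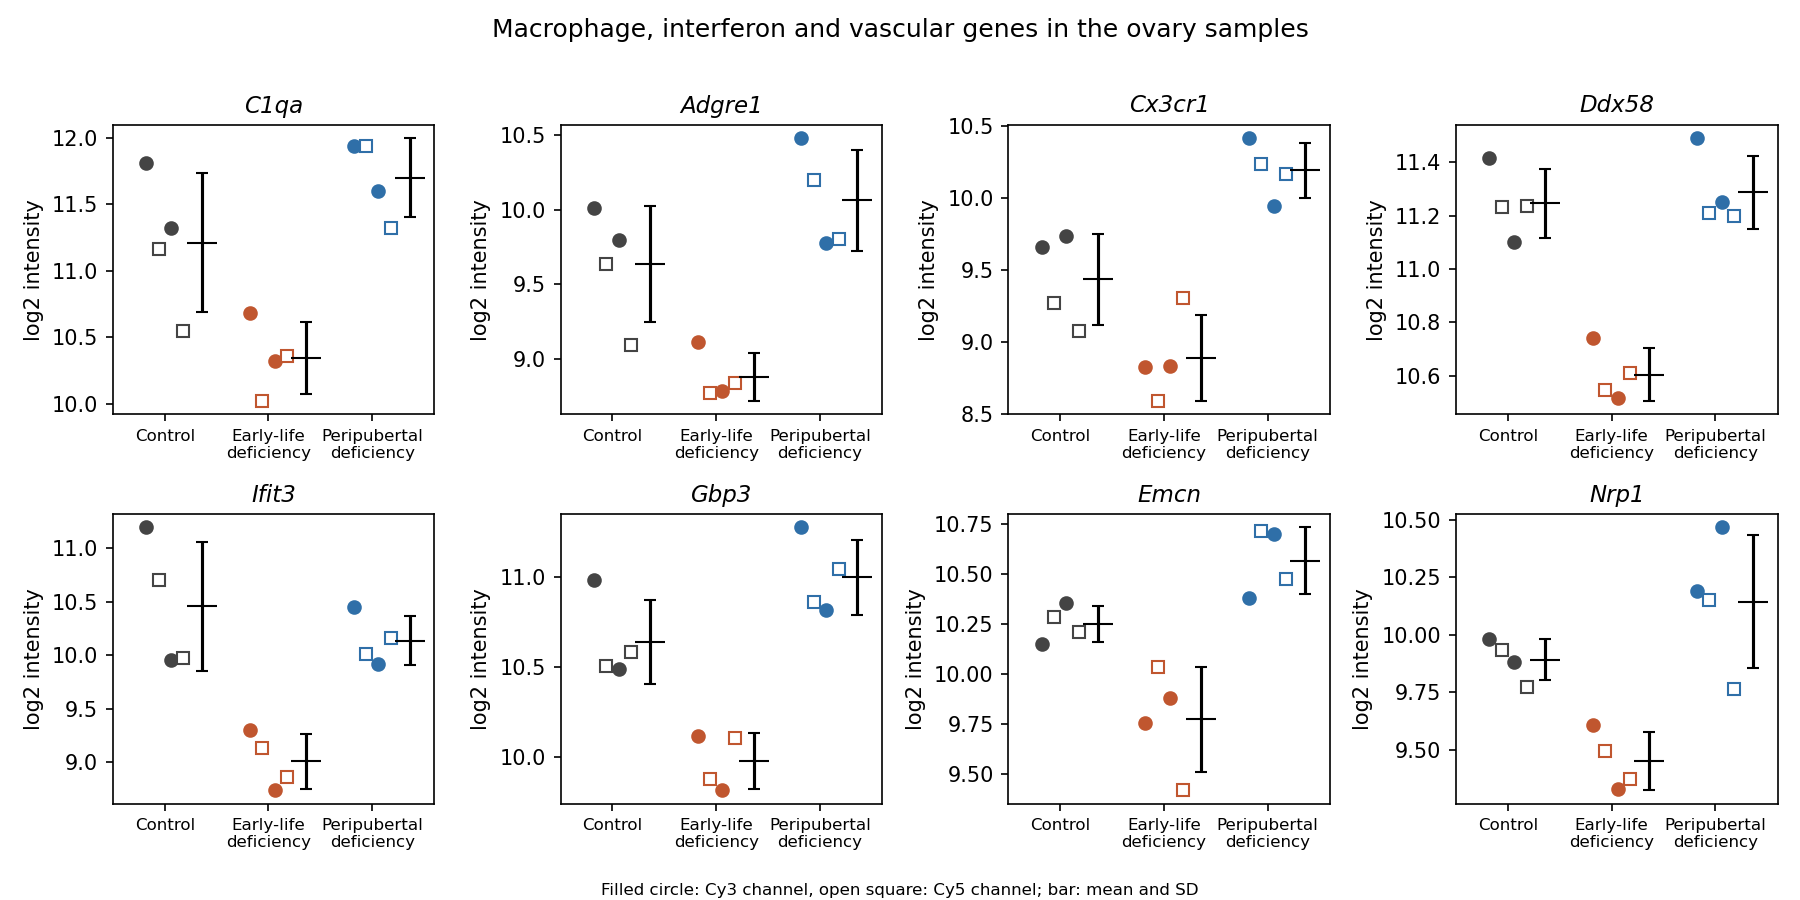
Log2 intensity of the macrophage genes C1qa, Adgre1 and Cx3cr1, the interferon genes Ddx58, Ifit3 and Gbp3 and the vascular genes Emcn and Nrp1, by diet group. Filled circles are Cy3 and open squares Cy5 samples, and bars are the mean and SD. C1qa is 11.21 ± 0.52 in control, 10.34 ± 0.27 in early-life and 11.70 ± 0.30 in peripubertal samples.

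Endothelial markers fell (median -0.34; camera adjusted p = 0.0452; adjusted p = 0.563 with an estimated correlation), with 4 members lower over the list alone and Emcn, at -0.80 ± 0.17 (adjusted p = 0.0443), over all genes. The angiopoietin receptor Tek differed by -0.53 ± 0.12 and the junction protein Esam by -0.67 ± 0.15, on 2 peripubertal values. Theca cell markers fell (median -0.47; adjusted p = 0.0452; adjusted p = 0.563 with an estimated correlation), with 4 lower over the list alone and 0 over all genes. Gli1, a transcription factor of hedgehog signalling, differed by -1.09 ± 0.31 and Aldh1a1, of retinoic acid synthesis, by -0.94 ± 0.30. Smooth muscle markers fell (median -0.66; adjusted p = 0.0355; adjusted p = 0.726 with an estimated correlation), with Mylk, at -0.85 ± 0.20, the 1 member over the list alone and 0 over all genes. Without 1 sample the theca list reached a camera adjusted p of 0.0533 without E2, 0.0783 without E4, 0.0932 without P2 and 0.0843 without P3, smooth muscle 0.0507 without E2 and 0.0932 without P2, and endothelium 0.0579 without E1, 0.0727 without P2 and 0.151 without P3.

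Oviduct epithelium markers rose (median 2.74; camera adjusted p = 4.20e-07; adjusted p = 0.563 with an estimated correlation), with 11 of 13 members higher over the list alone and 1 over all genes. That gene, Wfdc2 (probe on chromosome 2, 164393947 to 164394006), measured 13.20 ± 1.58 (SD, n = 4) in early-life and 8.70 ± 0.24 (SD, n = 4) in peripubertal samples, 22.7-fold higher (adjusted p = 0.0483). Elf3 differed by 2.74 ± 0.65 and Pax8, a transcription factor of the reproductive tract, by 2.82 ± 0.93. The oviduct score was higher in early-life samples in 16 of 16 pairs (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 samples allow, and 0.0857 adjusted over 3 comparisons). The permutation treats samples as exchangeable, though each array holds 2 samples of 1 group. With this score as a covariate the count of genes was 0, as the median standard error of the 471 genes grew from 0.115 to 0.158. Their median size went from 0.60 to 0.57, with 471 of 471 in the same direction and 470 at an unadjusted p under 0.05. With the covariate the oviduct list lost its call by construction. The theca and endothelial calls ended as well (camera adjusted p = 0.323 and 0.236, medians -0.50 and -0.23). Macrophage, interferon and smooth muscle genes still passed, with medians of -1.21, -0.91 and -0.79. The other lists had medians of -0.19 for vitamin D signalling, -0.52 for steroidogenesis, -0.39 for cholesterol synthesis and uptake, 0.020 for hormone receptors, -0.056 for LH-responsive periovulatory genes, 0.0060 for the TGF-beta, AMH and inhibin family, 0.0088 for the insulin and IGF axis, -0.34 for the WNT pathway, 0.052 for the cell cycle, 0.022 for apoptosis, -0.35 for extracellular matrix, -0.25 for angiogenesis, -0.072 for oxidative phosphorylation, 0.065 for immediate-early genes, 0.31 for heat shock, -0.17 for the circadian clock, 0.19 for oocyte markers, 0.034 for granulosa cell markers, -0.43 for luteal cell markers, 0.48 for ovarian surface epithelium markers, 1.12 for adipocyte markers, -0.087 for lymphocyte markers, -0.12 for granulocyte markers and 0.33 for red blood cell markers, with camera adjusted p of 0.0505 to 0.904.

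Beyond the lists, Cbs rose 11-fold (3.45 ± 0.75; adjusted p = 0.0445) and Pdzk1ip1 10.4-fold (3.38 ± 0.71). Snd1 was 3.40-fold higher, with the smallest adjusted p of the comparison (0.00125), and it passed whichever 1 sample was left out. Gulo, an enzyme of vitamin C synthesis, rose by 1.55 ± 0.29, the fibrillin Fbn2 by 1.54 ± 0.28, Paip1 by 1.43 ± 0.19 and Chmp4b, of the membrane-scission machinery, by 1.22 ± 0.23. Another Paip1 probe differed by only 0.034 ± 0.11 between peripubertal and control samples, against -1.23 for the called probe. Other probes were not compared between early-life and peripubertal samples. Tmem175 rose by 1.54 ± 0.15 on 2 values in each group, and Tmc7 was at least 2.18-fold higher than in peripubertal samples at background. Among the falls, Vmn2r28 was at least 12.8-fold, Svs3a at least 3.65-fold and Cd300ld4 at least 4.18-fold lower in early-life samples at background, the last on 2 peripubertal values. Slc11a1, a phagosomal metal transporter, differed by -2.22 ± 0.48, and Pdcd1, the immune checkpoint receptor PD-1, by -1.79 ± 0.37. The cytochrome P450 Cyp4f14 differed by -2.03 ± 0.26, the asialoglycoprotein receptor Asgr1 by -1.71 ± 0.36, the olfactory marker protein Omp by -1.93 ± 0.30, Clec18a by -2.51 ± 0.56 and Islr2 by -2.06 ± 0.31. Pdzk1ip1 was above background in 2 of 4 peripubertal and Clec18a in 2 of 4 early-life samples. All values of the groups lay apart in these 19 genes, with adjusted p of 0.00125 to 0.0473.

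Unadjusted p was under 0.05 in 4446 genes, and groups did not overlap in 4524 genes (24.4%). Here too the 2.86% that holds for independent values does not apply. Of the 471 genes 242 differed by at least 1.5-fold, 29 had fewer than 4 values in a group, 9 were at background in early-life and 7 in peripubertal samples. Without 1 sample the count was 226 without C1, 127 without C2, 100 without C3, 2 without E1, 1578 without E2 (881 higher, 697 lower), 3 without E3, 164 without E4, 42 without P1, 78 without P2, 273 without P3 and 188 without P4. Of the 38 named genes called here, Snd1 was called whichever sample was left out, and the others lost the call without 2 to 10 of the 12 samples. Lists that passed numbered 11 without C1, 10 without C2, 11 without C3, 11 without C4, 10 without E3 and 11 without P4. The count of genes was 1 without the scaling between arrays, 1 on array means, 9 with only the 2 groups in the model, 231 with the software's processed signals, 302 with the mean of probes, 759 without the dye term, 1230 with the intraspot model and 2099 without the array block. Of the 6 lists 0 passed with an estimated correlation (0 with an unadjusted p under 0.05), while fry called 4 lists, steroidogenesis, WNT, endothelium and macrophage, at an adjusted p of 0.0273.

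The hormone and vitamin D genes fixed in advance did not pass in any of the 3 comparisons, with adjusted p of 0.153 (Esr2, early-life versus peripubertal) to 0.994 (Gdf9, in that comparison). Vdr measured 8.22 ± 0.31 (SD, n = 4) in control, 8.45 ± 0.27 (SD, n = 4) in early-life and 8.54 ± 0.37 (SD, n = 4) in peripubertal ovaries. Cyp24a1, which inactivates vitamin D, was above background in 0 of 12 samples and was not tested, and Cyp27b1, which activates it, was near background, above it in 2 control, 4 early-life and 1 peripubertal samples of 4 each (7.10 ± 0.026, 7.01 ± 0.053 and 7.08 ± 0.060). Star, the cholesterol transporter of steroid synthesis, measured 14.64 ± 1.57, 12.70 ± 1.13 and 13.97 ± 1.28 in control, early-life and peripubertal samples (n = 4, 3 and 3). The steroid enzymes Cyp11a1, Cyp17a1 and Cyp19a1 differed from control by -0.20 ± 0.33, 0.95 ± 0.90 and -0.41 ± 0.91 after early-life and by 0.34 ± 0.33, 1.13 ± 0.90 and 0.26 ± 0.96 after peripubertal deficiency. The gonadotropin receptors Fshr and Lhcgr differed from control by 0.32 ± 0.31 and 0.20 ± 0.60 after early-life and by 0.035 ± 0.33 and -0.29 ± 0.60 after peripubertal deficiency. The steroid receptors Esr1 and Esr2 differed by 0.69 ± 0.48 and 0.59 ± 0.22 between early-life and peripubertal samples, and Pgr was too dim for a difference, above background in 1 control, 3 early-life and 1 peripubertal samples. Amh, which marks growing follicles, differed from control by -0.15 ± 0.26 after early-life and -0.33 ± 0.26 after peripubertal deficiency. The inhibin subunit Inha differed from control by -0.081 ± 0.17 and -0.13 ± 0.18, and the oocyte factor Gdf9 by 0.24 ± 0.25 and 0.23 ± 0.30, in the same order.

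The effects of early-life and peripubertal deficiency share the same controls, which alone makes them move together. The covariance of the fold changes was -0.0039 across 16828 genes with a value on all arrays, against 0.038 ± 0.050 (SD) in 1000 simulated draws with no effect, of which 844 were as large or larger. With the controls split between the effects it was -0.041 and -0.030. The correlation across genes was -0.031, against 0.43 ± 0.51 (SD) in the simulated draws, and genes are not independent replicates. With the groups as in the scanner labels, no shared effect of both deficiencies was detected beyond that of the shared controls. The simulated values spread so widely that a moderate shared effect would also have been missed, so this excludes none. Over all 18559 genes the covariance was -6.6e-04, and it was 0.0090 without C1, 0.010 without C2, 0.018 without C4, -0.012 without E2 and 0.0083 without P1. With the control and early-life arrays exchanged it was 0.15, above the simulated mean of the groups as labelled, and no simulation was run for the exchanged groups.

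The deposited value table, which was used in no comparison of genes but as an alternative, differed from the scanner files in its 4 peripubertal columns as well. These matched no scanner channel, with a best correlation across features of 0.874 to 0.897. Hormone genes of the pituitary gland stood far above the other 8 columns in them. Gh, growth hormone, was 10.10 ± 0.14 (SD, n = 4) against -2.79 ± 1.31 (n = 8), prolactin, Prl, 9.67 ± 0.33 against -2.14 ± 0.11 (n = 4), and Pomc, the precursor of corticotropin, 9.47 ± 0.82 against 0.74 ± 0.83 (n = 8). The median difference of 22 pituitary genes was 7.40 and 18 were higher in every value. Ovarian genes were lower in these columns, by medians of -5.29 for steroidogenesis, -4.68 for oocyte and -4.77 for granulosa cell genes. In the peripubertal scanner channels 14 of the 22 pituitary genes were above background in no sample, and their median difference from the other channels was 0.015.

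**Figure D3:**
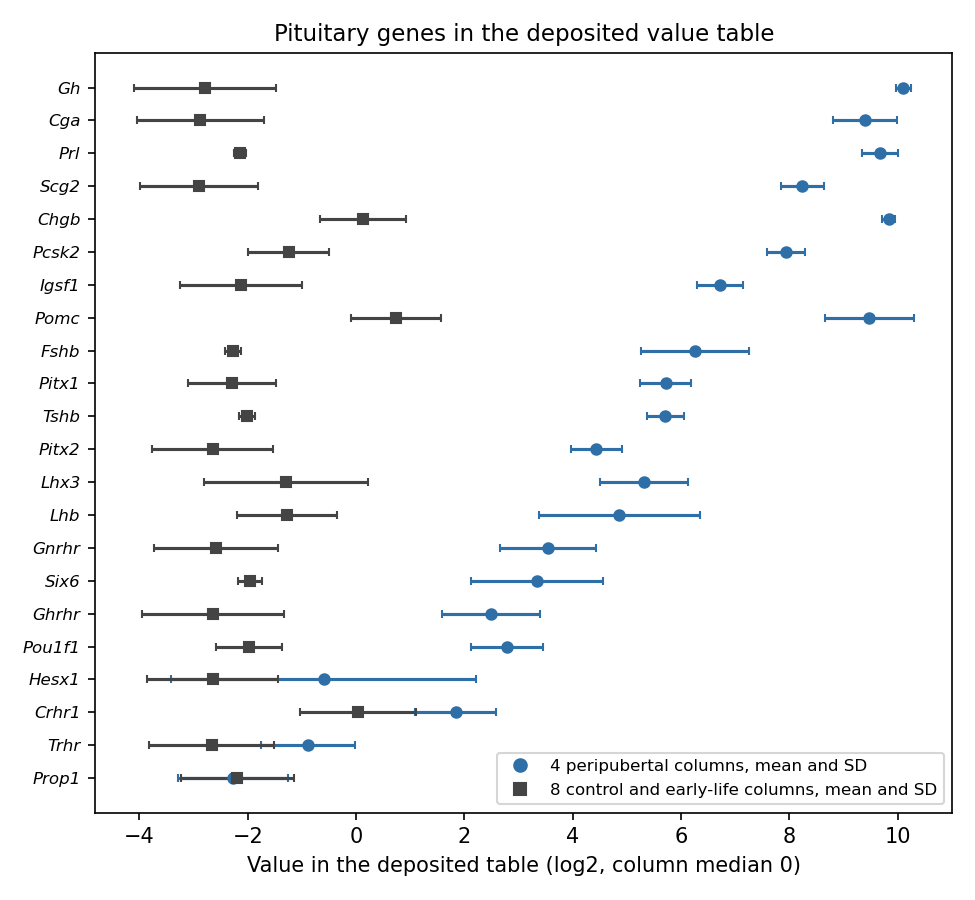
Log2 value of 22 pituitary genes in the deposited value table, mean and SD of the 4 peripubertal columns and of the 8 control and early-life columns. Gh is 10.10 ± 0.14 in the peripubertal columns and -2.79 ± 1.31 in the others.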

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

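The tests of reversed array positions, exchanged names, pituitary and brain genes, the diet groups alone and the linear trend with the oviduct score, and that of the score within equal replicate numbers, were chosen only after the result was seen, as were the exchange of arrays and the oviduct score as covariate.

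In the deposited value table all 8 control and early-life columns matched best the channel of the same dye at the mirrored position of the slide (correlation at least 0.9998, next best at most 0.99), and 0 matched the same replicate number of the other group, which argues against names exchanged with numbers kept. With the software's processed signals the same 8 positions matched best, but only 4 above 0.99 (0.983 to 0.994), and the other signal was tried after that. In the 4 peripubertal columns pituitary genes stood above the other columns by a median of 7.40, with 18 of 22 (81.8%) higher in every value, while brain genes stood above them by 0.545, which argues against brain. On the features with a value in all columns, the form of the test run at the start, 8 of 11 were higher (72.7%, under the share set for the test; median 8.73), and the form with all available values was chosen after that. Array positions reversed in 1 of the deposits and pituitary RNA in the table's peripubertal columns are candidate explanations that stay open. Neither says which deposit names the control and early-life arrays correctly. In the table's peripubertal columns, steroidogenesis, oocyte and granulosa cell genes were lower by medians of -5.29, -4.68 and -4.77, which argues against ovary there. In the peripubertal scanner channels these lists differed from control by medians of 0.20, 0.075 and 0.0084. No biological explanation was tested.

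Oviduct epithelium markers rose in early-life against peripubertal ovaries together with the 471 calls. Oviduct epithelium in the samples in differing amounts is a candidate explanation. Of 20 motile cilia genes outside the list, 18 were measured. They followed the oviduct score within groups (median correlation of deviations 0.952, range -0.0056 to 0.993, against -0.036 for all genes). The oviduct list itself holds cilia genes, Foxj1 among them, so this shows cilia genes moving together. It does not tell differing amounts of oviduct from another cause of that. Of the list, 2 markers named after their values were seen reached 15.60 ± 2.88 (Ovgp1) and 12.13 ± 1.76 (Foxj1) in early-life samples. They reached 9.70 ± 1.56 and 7.72 ± 1.37 in peripubertal samples, which restates the rise of the list. Of the 13 markers 9 were above background in all peripubertal samples and 0 are in another list. The labels name no step that would remove oviduct. With the score as covariate the median size of the 471 calls went from 0.60 to 0.57 (ratio 0.956). Of these, 471 kept their direction and 470 had an unadjusted p under 0.05. The count fell to 0 as the median standard error grew from 0.115 to 0.158. This cannot decide on a linear trend with the score as the whole cause. The calls favour genes with a small spread within groups, while the score had an SD of 1.44 in early-life samples. Genes that follow the score were thus less likely to be called. The diet groups alone stay open, as 14 of 16 pairs of an early-life and a control sample had the higher score in the early-life sample and the other 2 involve E2, 1 sample that decides nothing, while within equal replicate numbers 4 of 4 did (exact sign-flip permutation p = 0.125), and so does the slide, which cannot be told apart from the peripubertal group.

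Between peripubertal and control ovaries 50 genes were called, of which 6 have another probe above background. Signal of single probes is a candidate explanation, since those 6 other probes showed a median of 0.140 of the called change, with 4 of 6 in its direction and 0 of 6 at an unadjusted p under 0.05. The slide cannot be told apart from the peripubertal diet for these genes, as 0 slides hold peripubertal samples and another group. With the oviduct score as covariate all 50 kept their direction and an unadjusted p under 0.05, with a median size of 0.94 before and 0.93 after, and 0 were called as the median standard error grew from 0.134 to 0.147. The diet itself stays open and untested against these.

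Each comparison was set against the 35 splits of its 8 samples into equal groups. Each array holds 2 samples of 1 group, and 3 of the 35 splits, the real one included, keep the arrays whole, which are too few for a share under 0.05. The splits also ignore replicate numbers. Deviations of equal numbers correlated over 0.1 in 4 of 4 early-life and control pairs, and in 3 of 4 with the dye effect removed. For genes the real split gave 50 calls between peripubertal and control (at most 6 in another split, 1 of 35 splits as large; 2 and 6 in the other whole-array splits) and 471 between early life and peripubertal (at most 4, 1 of 35; 0 and 0). For early life versus control the real split gave 0 calls, so that 35 of 35 splits are as large by construction (4 and 5 in the other whole-array splits). Its highest other split, with 901, sets C1, E1, E3 and E4 against the others and points to a structure of the samples. These are 4 of the 5 samples with the highest oviduct scores, C4 being the other. C4 scored above C1, and the split of C4, E1, E3 and E4 against the others gave 306. How far the score accounts for these counts was not tested. For lists the real split gave 14 in early life versus control (17 in the highest other, 2 of 35 splits as large; 3 and 3 in the other whole-array splits), 3 in peripubertal versus control (14, 33 of 35; 1 and 8) and 6 in early life versus peripubertal (16, 26 of 35; 5 and 6).

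Between early-life and peripubertal ovaries 471 genes differed in the direct test. The slide cannot be told apart from the peripubertal group, so a difference of the diet effects cannot be read from it alone. With the control and early-life arrays exchanged the count was 50. It was 2 without E1 and 1 on array means.

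A sample stood apart from the other 3 of its group in 23 of 523 groups of 4 values tested (4.40%, against about 5% by chance), by Dixon's ratio of its gap to the range. Among control samples the ratio was 0.837 for Cd3d, 0.859 for Cfd, 0.887 for Cyp17a1, 0.851 for Mcm5, 0.862 for Paip1, 0.855 for Prcc, 0.833 for Prm1, 0.852 for Snd1, 0.833 for Svs3a, 0.993 for Vmn2r28 and 0.8292 for Zfp608. Among early-life samples it was 0.928 for Islr2, 0.838 for Lhcgr, 0.921 for Mx2, 0.881 for the mean of the apoptosis list and 0.877 for that of the theca list. Among peripubertal samples it was 0.935 for Bcl2l11, 0.879 for Ccdc39, 0.953 for Cd3d, 0.936 for Foxj1, 0.835 for Islr2, 0.861 for Kif20a and 0.848 for Wfdc2.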

How the results depend on the processing

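The exchange of control and early-life arrays, the oviduct score as covariate and the test of that score within equal replicate numbers were chosen only after the result was seen; the other alternatives were planned. The number of genes called in early life versus control (0) was 5 without background subtraction, 21 with the software's processed signals, 4 with quantile scaling, 255 (165 higher, 90 lower) on the deposited value table, 1 with outlier spots kept, 116 without the array block, 10 with the intraspot model, 35 without the dye term and 6 with trend and robust variance. In peripubertal versus control (50) it was 0 with loess but no Aquantile, 12369 on the value table, 21 with no filter, 14 with probes above background in all samples, 19 with the mean of probes, 26 with outlier spots kept, 159 without the array block, 1 on array means, 81 without the dye term, 14 with the replicate block, 0 with only the 2 groups, 471 (375 higher, 96 lower) with the arrays exchanged and 0 with the oviduct score; processed signals gave 68, of which 41 were higher, against 19 of 50. In early life versus peripubertal (471) it was 231 with processed signals, 1 with no Aquantile, 12842 on the value table (63.1% higher), 302 with the mean of probes, 2099 without the array block, 1230 with the intraspot model, 1 on array means, 759 without the dye term, 9 with only the 2 groups, 50 with the arrays exchanged, 0 with the oviduct score and 242 with a change of at least 1.5-fold, which holds by construction. The arrays exchanged turn these 2 comparisons into each other by construction; 28 genes were called in both. The peripubertal columns of the value table match no array, so of these 2 comparisons only the counts are given on it, not single genes or lists. These columns also enter the spread behind the early life versus control results on it. The number of lists in early life versus control (14) was 7 with the oviduct score, which takes out the oviduct list by construction, 0 with an estimated correlation and 0 with fry. In peripubertal versus control (3) it was 6 with processed signals, 6 with no Aquantile, 18 on the value table, 7 on array means, 6 with the arrays exchanged, 0 with an estimated correlation and 0 with fry. In early life versus peripubertal (6) it was 11 with quantile scaling, 10 with no Aquantile, 17 on the value table, 11 with the mean of probes, 10 with outlier spots kept, 3 with the intraspot model, 10 on array means, 10 without the dye term, 12 with the replicate block, 11 with only the 2 groups, 10 with trend and robust variance, 3 with the arrays exchanged and 0 with an estimated correlation. The fold change covariance (-6.6e-04 over all genes) was 0.080 on the value table, 0.011 with no filter, 0.0089 with probes above background in all samples, 0.15 with the arrays exchanged and 0.019 with the oviduct score. Except where said, the cause was not tested. Alternatives not given here kept each count within 1.5 times. With no Aquantile the median of all genes moved to 0.11 in early life versus control, and on the value table it was -0.18 and 0.25 in the peripubertal comparisons. Leaving out 1 sample or 1 array gave 0 to 108, 0 to 152 and 2 to 1578 genes in early life versus control, peripubertal versus control and early life versus peripubertal, 9 to 14, 1 to 5 and 5 to 11 lists in this order, and a covariance of -0.013 to 0.036. Without E2 (881 higher, 697 lower), without E3 (2 and 1) and without the array of E1 and E2 (18 and 5) or of E3 and E4 (28 and 23) in early life versus peripubertal, and without P3 (10 and 8) or the array of P3 and P4 (102 and 50) in peripubertal versus control, more genes were higher than lower, the reverse of all samples. The ends were reached without E2 (108 and 1578), without E1 (2), without E3 (0 in peripubertal versus control), without the array of P3 and P4 (152), without C4 (1 list) and without the arrays of E1 and E2 (9 lists, -0.013) and of C1 and C2 (0.036).

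On the value table, where the groups are the other way round, all 88 named genes of early life versus control measured there turned their direction, 77 of them passing neither there nor in the scanner files. The other 11 passed there: Fam135a (-1.73), Olfr1357 (1.41), Creb3l2 (-2.01), Xpo7 (0.64), Zfp608 (-0.71), Gngt2 (0.83), Mvk (1.01), Igfbp7 (0.81), Ddx58 (0.75), Ifit3 (1.58) and Mx2 (0.94). The spread behind these calls includes the peripubertal columns that match no array. With the arrays exchanged Fam135a (-0.028), Mrgpra1 (0.12) and Cldn34b4 (0.16) turned in peripubertal versus control. All 14 list medians of early life versus control turned with the arrays exchanged, by construction, and 13 on the value table. They were 0.75 on the value table and 0.69 exchanged for cholesterol, 0.39 and 0.23 for cell cycle, 0.33 and 0.26 for angiogenesis, 0.30 and 0.14 for oxidative phosphorylation, -0.30 and -0.35 for immediate-early genes, 0.64 and 0.58 for interferon, -0.16 and -0.24 for oocyte, -0.51 and -0.60 for surface epithelium, -1.79 and -1.64 for oviduct, -2.02 and -1.73 for adipocyte, 0.76 and 0.59 for smooth muscle, 0.82 and 0.75 for macrophage and -1.13 and -1.04 for red blood cells, and 0.26 exchanged for endothelium. Over the alternatives chosen in advance, samples left out included, named genes kept direction and side of the threshold in 2854 values of early life versus control, 1227 of peripubertal versus control and 2294 of early life versus peripubertal; 0, 342 and 559 fell short of it, and 78, 5 and 102 passed it anew. Another 88, 30 and 35 values turned their direction without passing in either, and 11, 0 and 0 turned and passed. Odd replicate numbers are in Cy3 and even ones in Cy5, so number and dye can be told apart only in part. The labels do not say that numbers pair samples, and the data do not settle it. The main model does not treat samples as pairs. As measured, deviations of equal numbers correlated over 0.1 in 4 of 4 pairs of early-life and control samples (0.147 to 0.587, all matching their own number best), 2 of 4 of peripubertal and control (1 matching best) and 0 of 4 of early-life and peripubertal samples (1 matching best). With the dye effect removed it was 3 of 4 (0.0711 to 0.545), 0 of 4 and 0 of 4, and 1, 0 and 0 matched best. Signal over background of 6.96 to 9.62 limits what dim probes show.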

Other observations

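The test of the cilia genes was written before its result was seen, and the 4 cilia genes named were chosen after their values were seen. Several gene groups that did not pass as lists held single genes that changed between early-life and peripubertal ovaries. The matrix genes Timp3 and Mmp2 were lower in early-life ovaries. Timp3, an inhibitor of matrix proteases, measured 13.43 ± 0.20 (SD, n = 4) in early-life and 14.34 ± 0.23 (SD, n = 4) in peripubertal samples and differed by -0.91 ± 0.19 (adjusted p = 0.0437), and the gelatinase Mmp2 by -1.28 ± 0.29. Over the list alone 3 matrix genes passed, all lower, and 2 over all genes. In the insulin and IGF axis Igfbp7 differed by -1.08 ± 0.20 (adjusted p = 0.0361) and Igf2r, which clears IGF2, by 0.51 ± 0.10 (adjusted p = 0.0401), the former lower and the latter higher in all early-life samples; these 2 passed over the list alone and over all genes. Lrp5, a co-receptor of WNT signalling, differed by -0.46 ± 0.093 (adjusted p = 0.0401) and was the 1 WNT gene that passed either way.

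Among apoptosis genes Pmaip1 (Noxa), which promotes cell death, and Birc2, which restrains it, were both lower in early-life ovaries, by -0.55 ± 0.10 and -0.49 ± 0.11 (adjusted p = 0.0351 and 0.0460), Pmaip1 being above background in 2 of 4 early-life samples, while Bcl2l11 (Bim), which promotes it, differed by 0.37 ± 0.094; Pmaip1 and Birc2 passed over all genes and all 3 over the list alone. Nrp1 differed by -0.69 ± 0.15 (adjusted p = 0.0457), the 1 of 4 angiogenesis genes passing over the list alone that also passed over all genes, and Ptprc by -0.69 ± 0.12 (adjusted p = 0.0277), 1 of 2 lymphocyte genes. In steroidogenesis 3 genes passed over the list alone and 0 over all genes. The smallest p were those of Akr1cl (-0.71 ± 0.16), Nr5a1, the transcription factor SF-1 (-0.67 ± 0.16), and Akr1c18, which inactivates progesterone. Akr1c18 measured 11.26 ± 1.83 (SD, n = 4) in early-life, 15.34 ± 1.16 (SD, n = 3) in peripubertal and 11.16 ± 0.22 (SD, n = 2) in control samples (early-life minus peripubertal -4.11 ± 1.1, adjusted p = 0.0939). In vitamin D signalling 3 genes were lower over the list alone and 0 over all genes. Cyp27a1, a vitamin D hydroxylase, was at -0.47 ± 0.11 and the parathyroid hormone receptor Pth1r at -0.94 ± 0.26. Rxrg, a partner of the vitamin D receptor, was at -0.32 ± 0.099. Of the 17 measured members 6 were higher and 11 lower, with a median of -0.19 but a mean of 0.10. Calb1, a member that did not pass, was higher in all 34 alternative settings, by 0.0019 to 4.11. Ltf, lactoferrin, was the 1 granulocyte list gene that passed over the list alone and none did over all genes. It measured 14.42 ± 2.27 (SD, n = 4) in early-life and 8.94 ± 0.66 (SD, n = 4) in peripubertal samples (limma adjusted p = 0.0905). The list as a whole did not rise: of its 5 measured members 2 were higher and 3 lower, with a median of -0.12. S100a8 and S100a9 were lower in every alternative setting (-1.76 to -0.39 and -1.48 to -0.62).

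Motile cilia genes outside the oviduct list were measured in 18 of 20 cases. Of these, 17 were higher in early-life than in peripubertal means, with a median of 1.86, and the median against control was 1.32. The dynein gene Dnah5 differed by 3.02, Cfap52 by 2.98 and Hydin by 2.52 between early-life and peripubertal samples, and 0 of the 18 passed the limma test of that comparison over all genes, the smallest adjusted p being 0.0790 for Mns1.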
